A study of Homo sapiens with 44 samples.

How the data were processed

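Total RNA depleted of ribosomal RNA was sequenced from HAP1 cells as stranded libraries, in biological duplicates, per the labels' protocols. The hgRNAs were delivered by lentivirus with puromycin selection for 48 h, and RNA was taken 3 days later, per the labels. Per the labels, the siRNA knockdowns were harvested at 48 h, and the knockouts combined an exonic Cas9 guide with an intergenic Cas12a guide. The libraries titled SRSF3 deletion were treated as such, since their guides match SRSF3 sequence, although their treatment label names SON.

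The authors deposited 3 tables. The first holds, per the file headers, pooled RPKM in 21 columns and 19 comparisons, each with a log2 fold change, a p-value and an FDR. The submitters' processing notes list Salmon 1.10 and edgeR, without saying which value each made. Its duplicates are combined into single columns, so no per-library expression was analysed here, and no spread between replicates can be given for expression. Of 62269 genes in the authors' deposited table, 25373 have fold changes. The second table holds percent spliced in for each library, with values in percent per the file headers, and a text with the coverage score and the reads for and against inclusion. Its event names are those of vast-tools, and the aligner settings, version and genome build are not given in the sources used here. The third deposited table holds a pooled PSI score per group, which reaches 107, and a significance score in steps of 0.01, per the file headers. That significance score is not defined in those sources and was not used. Of the columns in the per-library table, 4 named TKO.ctrl match no sample and were not used. Their name reads as a control of the knockouts, which were set against the intergenic controls here.

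Coordinates were checked before use: 48152 of 60296 exon events (79.9%) coincided exactly with an exon of GENCODE v29, whose build is GRCh38. The pooled PSI of the intergenic control correlated at r = 0.9999 with the mean of the 4 control libraries over 159450 events, which is the basis for reading that pooled column as all 4. Each of the 36 guides in the labels was matched with its PAM to GENCODE v29 transcripts. Of these, 18 were placed in the targeted gene and 18 were not placed. Guides in introns without transcript sequence cannot be placed this way.

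Libraries were grouped by condition as the labels give them, with both hgRNAs of a gene in 1 condition. Events were tested when the coverage score was LOW or better in every library of the conditions compared and the mean PSI over all libraries was between 1 and 99. Of 721536 events in the table, 378704 had such coverage in at least 1 library. PSI was tested with limma 3.58.1 in 1 fit of all 44 libraries, which share 1 estimate of the spread, and events were called at a Benjamini-Hochberg adjusted p under 0.05 and a difference of at least 10 points. Microexons are exons of at most 27 nt. The limma prior had 1.99 degrees of freedom and an SD of 1.79 points. The difference between a deletion and the loss of the same gene was tested as a contrast in the same fit. Correlations of changes are given beside those simulated for unchanged groups against the same controls. The level of intron retention was the mean PSI over introns with a PSI of at least 15 in the control libraries not used for the comparison. It was compared by an exact two-sided permutation test, adjusted over 13 comparisons. Events inside a deleted interval were tested in the same way, over 3 events.

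The planned expression test on counts could not be run on pooled RPKM, and the fold changes, p-values and FDR of the authors' deposited table were used instead, with genes called at an FDR under 0.05. This replaced the design fixed before the data were examined. Sets were tested with cameraPR of limma on signed z-scores made from the deposited p-values, with a preset correlation of 0.01 and again with an estimated correlation, adjusted over 513 tests. The background was 16150 genes with at least 1 RPKM in a pooled column. The 27 lists were SR proteins, hnRNPs, speckle proteins, paraspeckle proteins, core spliceosome, factors of nonsense-mediated decay, transcripts sensitive to it, cap binding and exosome, replication-dependent histones, ribosomal proteins, ATF4 targets, chaperones of the endoplasmic reticulum, p53 targets, interferon response, G2/M, G1/S, actin and SRF targets, YAP targets, immediate-early genes, heat shock, cholesterol synthesis, hypoxia and glycolysis, SON-dependent genes, mitochondrial RNAs, and blood, neuronal and fibroblast genes. Medians and means of a list had the same sign as its test wherever the report gives a call.

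The lists, the tests, the thresholds, most alternatives and the rules for naming were chosen before the data were examined. Genes were named from the 8 largest rises and 8 largest falls per condition at a level of at least 5 RPKM, the planned minimum having been in counts, and from list members with small p. Events were named from the 3 introns and 3 exons with the largest rise and fall on which all perturbed libraries stood outside the controls, and from called events of the targeted genes. Genes called with both hgRNAs of a deletion, genes behind counts of 5 or fewer, the TAF15 event and some list members given as examples, were chosen after their values were seen. For chromosome arms, medians cover genes more than 50 kb from the targeted gene up to the telomere. They are among 13270 genes with a position and a mean of at least 1 RPKM.

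The tests were tried on simulated data. In the PSI model, 50 events each were changed by 10, 15, 20 and 30 points in the same data, among 51329 events. The noise was normal, with no separate spread between hgRNAs. A change of 20 points was recovered in 94% of events for a deletion, 94% for a knockout and 88% for a knockdown. A change of 10 points was recovered in 44%, 38% and 38%, where 80%, 64% and 62% passed the adjusted p alone. Many changed events ease the adjusted threshold, so recovery may be lower where few events change. The mean chi-square of read counts between duplicates was 2.28 to 3.66 over 22 pairs, so duplicates differed by more than read sampling, and no pair held the same library. Software was Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, matplotlib 3.10.9 and R 4.3.3. Alternatives covered the PSI scale, the difference and coverage minimums, the libraries fitted, the grouping, a replicate block, leaving out each library, the fold-change minimum, the intron minimum and the set correlation.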

Results

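RNA was sequenced in 44 libraries of HAP1 cells, a near-haploid human line derived from a chronic myeloid leukaemia. The libraries came from 15 conditions in 22 groups of biological duplicates. In 6 conditions a segment of PFN1, SFPQ, SON, SRRM2, SRRT or SRSF3 was removed with a hybrid guide RNA (hgRNA), a single transcript that guides Cas9 to 1 end of the segment and Cas12a to the other. Each of these genes had 2 hgRNAs and so 4 libraries, and 4 libraries with intergenic deletions served as controls. Exonic Cas9 knockouts of PFN1, SON, SRRM2 and SRRT, with 2 libraries each, were compared with the same 4 controls, as in the authors' deposited table, so their differences include any that lies between the library sets. Knockdowns of SRSF3, SRRM2 and SFPQ with small interfering RNA (siRNA), 2 libraries each, were compared with 2 libraries of non-targeting siRNA. The splicing value was the percent spliced in (PSI), the share of informative reads that include an exon or retain an intron. The median number of informative reads in a library was at least 87 over 54858 introns and ranged from 138 to 284 over 60296 exons.

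The level of each targeted gene was read first, as a check of the labels. SRSF3, an SR protein that binds exons, fell with its siRNA, with a log2 fold change of −3.31 and an FDR of 1.3e-102 in the authors' deposited table. SFPQ, an RNA-binding protein of paraspeckles, fell with its siRNA by 2.86 on the log2 scale in the authors' deposited table (FDR 3.4e-86). SRRM2, a scaffold protein of nuclear speckles, fell with its siRNA by 2.48 on the log2 scale in the authors' deposited table (FDR 2.1e-17). PFN1, the actin-binding protein profilin, fell in its knockout by 1.40 on the log2 scale in the authors' deposited table (FDR 1.8e-20). SON was not called in its knockout in the authors' deposited table, with a log2 fold change of −0.06. In the authors' deposited table, SRRM2 was not called in its knockout either, with a log2 fold change of −0.37 and 95.3 against 170.6 RPKM. SRRT, which joins the nuclear cap-binding complex to RNA decay, was not called in its knockout in the authors' deposited table, with a log2 fold change of −0.03. A transcript that carries a small exonic deletion can keep its level, so for these 3 genes the level neither checks nor contradicts the label.

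Among the deletions, the level of PFN1 fell with both hgRNAs in the authors' deposited table, by 0.51 (FDR 0.0285) and 1.06 (FDR 9.2e-11) on the log2 scale. SRRT rose with hgRNA 2 in the authors' deposited table, with a log2 fold change of 0.47 and an FDR of 0.0132, and was not called with hgRNA 1 at 0.20. The other 4 genes were not called in the authors' deposited table, with log2 fold changes of 0.18 and 0.20 for SFPQ, −0.21 and −0.32 for SON, −0.36 and −0.19 for SRRM2, and 0.04 and 0.09 for SRSF3. Other genes between SON and the telomere had medians in the authors' deposited table of −0.21 with hgRNA 1 and −0.31 with hgRNA 2 over 78 genes. As the log2 ratio of pooled RPKM, an alternative chosen after the data were seen, SON itself was at −0.0336 with hgRNA 1. For PFN1 the medians of the genes on that side in the authors' deposited table were −0.38 with hgRNA 1 and −0.40 with hgRNA 2 over 69 genes.

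Both ends of the deletion could be placed for SRRM2 and SRSF3. The SRRM2 guides enclosed 242 bp with hgRNA 1 (GRCh38, chromosome 16, 2759913 to 2760154), and the segment from 2759901 to 2760062 with hgRNA 2. Both intervals overlapped a cassette exon (HsaEX0061788, 2759747 to 2760008), which the labels describe as carrying a premature stop codon, and a retained-intron event around it (HsaINT0159182, 2759662 to 2760300). Retention of this SRRM2 intron was 56.2% ± 3.10 (SD, n = 4) in the intergenic controls and 25.5% ± 14.1 (SD, n = 4) in the deletion. Inclusion of the SRRM2 exon was 19.4% ± 2.54 (SD, n = 4) in the controls and 10.7% ± 5.51 (SD, n = 4) in the deletion. In an exact two-sided permutation test, chosen after the limma result was seen, both SRRM2 events gave p = 0.0286 (adjusted over 3 events, 0.0286), the smallest p that 4 against 4 libraries allow. The limma test over all events called neither, with adjusted p = 0.235 for the intron and 0.546 for the exon. The targeted intron was called in a fit without the knockout libraries, chosen after the data were seen. A fall was not particular to it. An SRRM2 intron outside both intervals (HsaINT0159172, 2769285 to 2770351) was at 23.1% in the deletion and 41.2% in the controls (limma, adjusted p = 0.841). Its differences were −24.8 points with hgRNA 1 and −11.3 with hgRNA 2, so the fall of the targeted intron cannot be ascribed to the lost segment alone.

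By single hgRNA, retention of the SRRM2 intron was 13.5% with hgRNA 1, which limma called at an adjusted p of 0.0215, and 37.6% with hgRNA 2, which was not called (limma, adjusted p = 0.508). Inclusion of the SRRM2 exon was 5.95% with hgRNA 1 (limma, adjusted p = 0.0342) and 15.4% with hgRNA 2 (limma, adjusted p = 0.859). In the deletions of the other 5 genes the means per hgRNA ranged from 31.3% to 55.7% for the intron and from 12.1% to 19.6% for the exon, a range that holds the values of SRRM2 hgRNA 2. The same SRRM2 exon was lower in the SON knockout, at 6.71% (limma, adjusted p = 0.0185), and in the SRRM2 knockout, at 8.44% (limma, adjusted p = 0.036). The call was lost without SON knockout replicate 1 (−9.51 points) or intergenic control hgRNA 2 replicate 2 in the first, and without 4 of the 6 libraries compared in the second. For SRSF3, the guides enclosed 846 bp (chromosome 6, 36599989 to 36600834) with hgRNA 1 and 776 bp (36600071 to 36600846) with hgRNA 2. Both lay within a retained-intron event of SRSF3 (HsaINT1042969), whose mean was 2.00% in the deletion and 3.58% in the controls (exact permutation test, p = 0.0286), which limma did not call (adjusted p = 0.847). The change was not particular to this intron, since 2 SRSF3 introns outside the intervals were at 0.865% and 1.05% in the deletion and 2.15% and 2.13% in the controls.

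**Figure D1:**
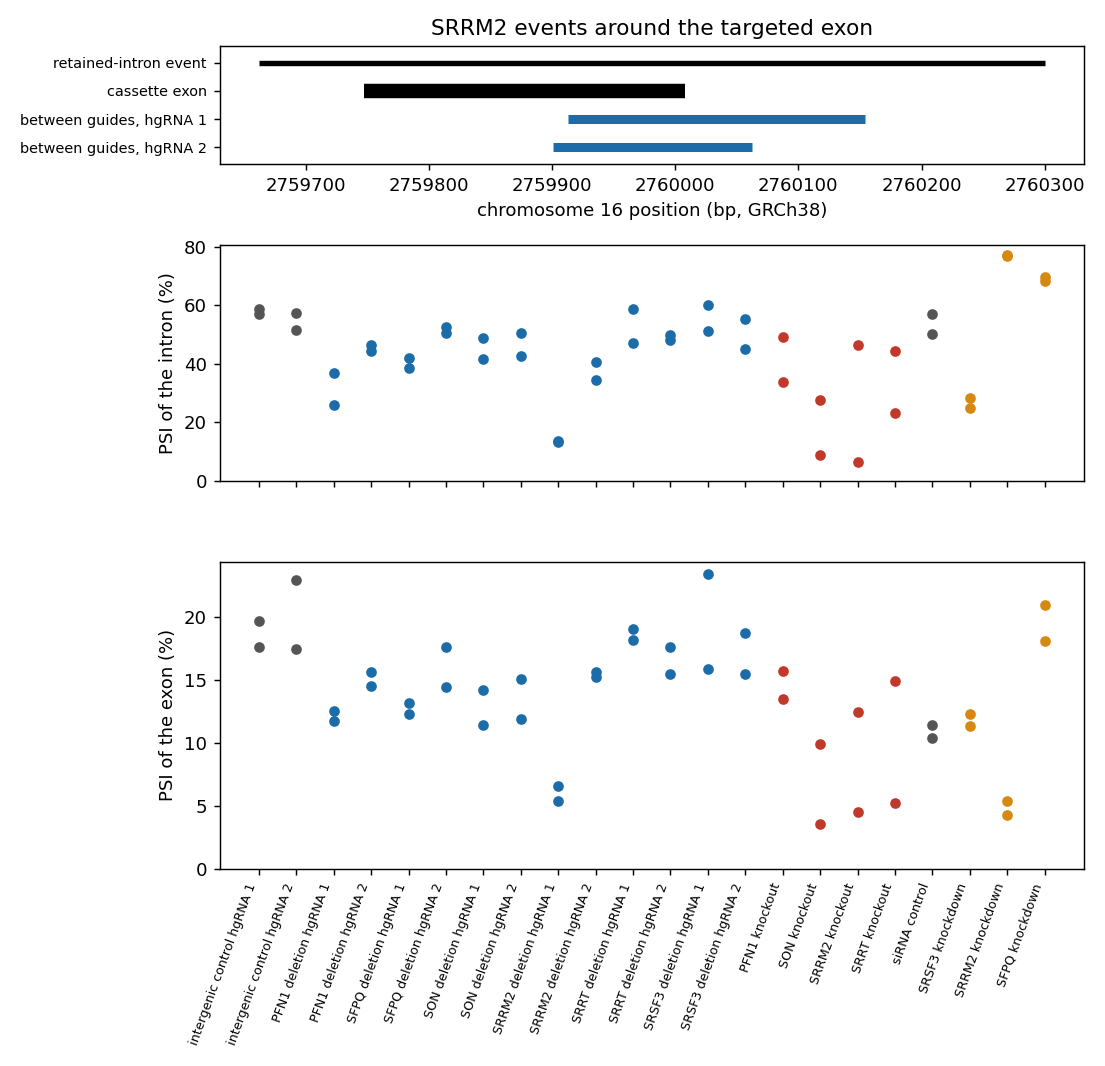
The upper panel places the SRRM2 intron and exon events and the intervals between the guides on chromosome 16 (GRCh38 position in bp), and the lower panels give the PSI in percent of the intron and the exon for each library (points) by group. Retention of the intron averaged 56.2% in the intergenic controls, 13.5% with SRRM2 hgRNA 1 and 37.6% with SRRM2 hgRNA 2.

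The intronic deletions were compared with intergenic deletions to ask which transcripts respond when the targeted segment is lost. Per the labels, the PFN1, SFPQ, SON and SRSF3 deletions lie in introns. Those of SRRM2 and SRRT span an exon with a premature stop codon, per the labels. Few splicing events changed in any of them. In the SON deletion 1 event was called, lower inclusion of an exon (HsaEX0022044, chromosome 3, 184315489 to 184315545) of EIF4G1, a scaffold of cap-dependent translation initiation. Its inclusion was 72.1% ± 1.85 (SD, n = 4) against 83.1% ± 1.68 (SD, n = 4), a difference of −11.1 points (SE 1.14; limma, adjusted p = 5.3e-06). This call was lost on the logit scale of PSI and in a fit of the 2 compared conditions only. In the SRRM2 deletion 4 events were called, 3 higher and 1 lower, of which 2 are alternative 5′ sites of the same exon of TAF15, an RNA-binding protein, and mirror each other. All 4 calls were lost on the logit scale of PSI and in a fit of the 2 compared conditions only. An exon (HsaEX0056418, chromosome 12, 124782683 to 124782811) of SCARB1, a receptor for high-density lipoprotein, was included at 26.5% ± 2.06 (SD, n = 4) against 14.04% ± 2.92 (SD, n = 4) (SE of the difference 1.71; limma, adjusted p = 0.00182). An intron (HsaINT0123561) of PGD, an enzyme of the pentose phosphate pathway, was retained at 20.8% ± 6.18 (SD, n = 4) against 4.56% ± 0.979 (SD, n = 4) (limma, adjusted p = 0.0429). The PGD call held without SRRM2 deletion hgRNA 1 replicate 1 (19.3 points). It was lost without each of the other 7 libraries compared (15.1 to 16.4 points).

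The limma test called 0 events in the deletions of PFN1 (3364 of 78995 events at an unadjusted p under 0.05), SFPQ (3070 of 79160), SRRT (3097 of 77102) and SRSF3 (4020 of 72371). With each hgRNA tested singly, hgRNA 1 and 2 called 3 and 0 events for PFN1, 0 and 0 for SFPQ, 2 and 0 for SRRT, 7 and 1 for SRSF3 and 3 and 1 for SON. In the same design, simulated changes of 15 points were recovered in 96% of 50 events and those of 10 points in 44%. With few changes in a deletion, recovery may be lower. The targeted SRRM2 intron moved by −30.7 points in its deletion and was not called. Without intergenic control hgRNA 1 replicate 2, 1 event was called for SFPQ, 1 for SRRT and 4 for SRSF3. Without SRRT deletion hgRNA 2 replicate 2, 1 event was called for SRRT, and without intergenic control hgRNA 2 replicate 1, 2 were called for SON. The hgRNAs of SRRM2 differed from each other at 81 events in limma's test of the difference. There, hgRNA 1 called 18 events and hgRNA 2 called 77, of which 3 were shared in direction. Both hgRNAs share their controls, so some agreement is expected without an effect.

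**Figure D2:**
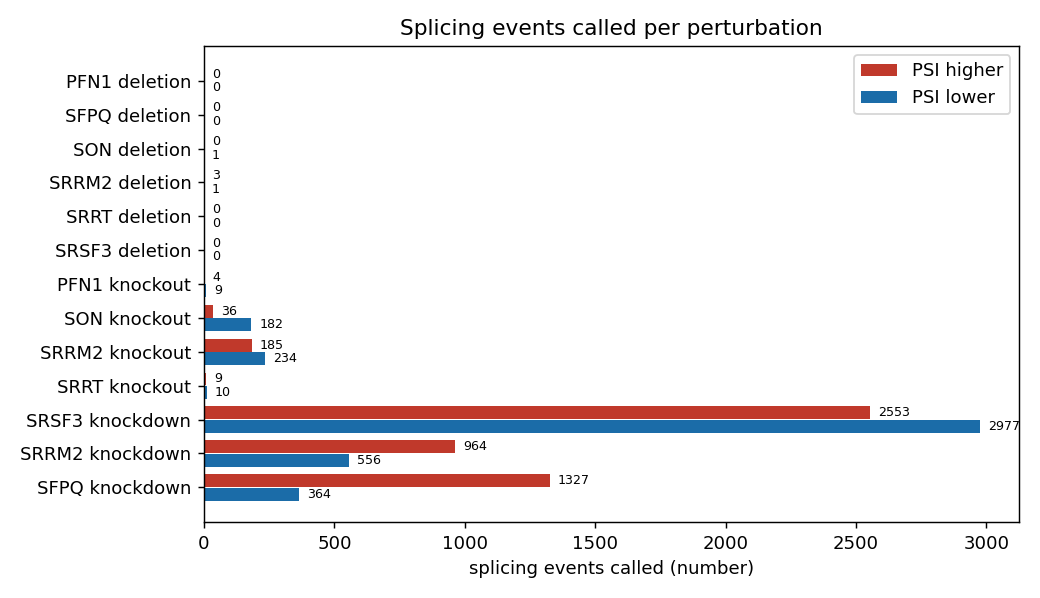
Bars give the number of splicing events called with a higher (red) or lower (blue) PSI in each comparison, at an adjusted p under 0.05 and a difference of at least 10 points. The 6 deletions called at most 4 events each, the knockouts 13 to 419, and the knockdowns 1520 to 5530.

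At the level of expression, YAP targets and actin and SRF targets were higher as sets with both hgRNAs of SFPQ at the preset correlation, and with an estimated correlation only the YAP list with hgRNA 2 was called. With hgRNA 1, 837 genes were higher and 260 lower, and with hgRNA 2, 33 were higher and 1 lower in the authors' deposited table. Both hgRNAs raised 27 genes in common in the authors' deposited table. Some agreement is expected from shared controls alone, and its size is not known here. The 27 included ANKRD1, a YAP target that encodes a muscle cofactor, the smooth-muscle genes TAGLN and ACTG2, and the epithelial keratins KRT8 and KRT18. The mean log2 fold changes in the authors' deposited table were 1.61 for ANKRD1, 1.47 for TAGLN and 1.13 for ACTG2. Of 16 YAP targets in the authors' deposited table, 7 were higher and 0 lower with hgRNA 1 (9 and 0 adjusted over the list alone), and 2 higher and 0 lower with hgRNA 2 (8 and 0). The limma set test called the YAP list with both hgRNAs, at an adjusted p of 7.8e-08 (adjusted p = 0.153 with an estimated correlation) and 2.1e-19 (0.00737). Of 37 actin and SRF targets in the authors' deposited table, 14 were higher with hgRNA 1 and 1 with hgRNA 2, with 0 lower in either (17 and 3 higher adjusted over the list alone). The limma set test gave adjusted p = 4.4e-06 and 1.1e-07 for this list, which became 0.153 and 0.0913 with an estimated correlation.

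The SRRM2 hgRNAs changed expression to very different extents. With hgRNA 2, 1000 genes were higher and 1078 lower in the authors' deposited table, and with hgRNA 1, 6 were higher and 4 lower (PI15, SLC12A3, MYOF and SPARC). Of the genes called with both, KCNK9, a potassium channel gene, was higher in both and 2 went opposite ways in the authors' deposited table. With hgRNA 2, ANKRD1 and TAGLN rose by 2.82 and 2.28 on the log2 scale in the authors' deposited table, and 10 of 16 YAP targets were higher and 0 lower (12 and 0 adjusted over the list alone). The limma set test gave adjusted p = 1.3e-12 for YAP targets (adjusted p = 0.036 with an estimated correlation) and 7.5e-07 for the 37 actin and SRF targets (0.128), of which 7 were higher. With hgRNA 1, the YAP list was lower as a set (limma, adjusted p = 0.00339, and 0.545 with an estimated correlation), with 0 of its genes called in the authors' deposited table. Of 26 targets of ATF4, which drives amino acid synthesis under stress, 3 were higher and 6 lower with hgRNA 2 in the authors' deposited table, such as PCK2 at −1.39 and DDIT4 at −0.97 (4 and 11 adjusted over the list alone). As a set they were lower at the preset correlation (limma, adjusted p = 0.00221) and not called with an estimated one (adjusted p = 0.224). Replication-dependent histone genes were higher as a set with hgRNA 1 (limma, adjusted p = 6.6e-09, and 0.221 with an estimated correlation), with 0 of 57 called, and 3 called adjusted over the list alone in the authors' deposited table.

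The PFN1 deletion lowered PFN1 itself and its neighbours METTL16, an RNA methyltransferase, and NXN, a redox protein, with both hgRNAs, and raised RMRP, the RNA of RNase MRP. Of all genes with hgRNA 1, 113 were higher and 34 lower in the authors' deposited table, and with hgRNA 2, 3 were higher (RMRP, SNORD3A and TEX12) and 6 lower. With hgRNA 1, fold changes in the authors' deposited table and log2 ratios of pooled RPKM correlated at 0.704, the lowest of 19 comparisons. Their signs matched in 69.95% of genes, so its counts are less certain. Mean log2 fold changes in the authors' deposited table were 0.92 for RMRP and −0.48 for NXN. Of 16 YAP targets in the authors' deposited table, 3 were higher and 0 lower with hgRNA 1 (7 and 0 adjusted over the list alone; limma set test, adjusted p = 1.4e-06, and 0.224 with an estimated correlation).

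In the SRSF3 deletion, the D-type cyclin genes CCND1 and CCND2, which drive entry into the cell cycle, were higher with both hgRNAs, as were TAGLN and HHIP, an antagonist of hedgehog signalling. Their mean log2 fold changes in the authors' deposited table were 0.79, 1.14, 0.85 and 0.67. Both hgRNAs lowered VPS52, which acts in retrograde transport, and shared 9 higher genes in the authors' deposited table. These hgRNAs share controls as well, and so do the deletions of different genes. CCND2 and TAGLN were also called higher with both hgRNAs of SFPQ, and CCND1 with both of SRRT. Their rises were thus not particular to SRSF3. The counts in the authors' deposited table were 25 higher and 26 lower with hgRNA 1, and 48 higher and 18 lower with hgRNA 2. Host genes of small nucleolar RNAs and other transcripts sensitive to nonsense-mediated decay were lower as a set with hgRNA 2, with 0 higher and 1 lower of 17 in the authors' deposited table (0 and 6 adjusted over the list alone). The limma set test gave adjusted p = 6.4e-07 for them, and 0.0386 with an estimated correlation. Neuronal genes were higher as a set with hgRNA 1 (limma, adjusted p = 2.9e-04, and 0.0248 with an estimated correlation), with 0 of 6 called in the authors' deposited table and 3 higher adjusted over the list alone.

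In the SRRT deletion, CCND1 was the gene called higher with both hgRNAs, as in the SRSF3 deletion, with a mean log2 fold change of 0.74 in the authors' deposited table. With hgRNA 1, 16 genes were higher and 11 lower in the authors' deposited table, and with hgRNA 2, 3 were higher (SRRT, CCND1 and INHBE) and 1 lower. Transcripts sensitive to nonsense-mediated decay were lower as a set with SRRT hgRNA 2 (limma, adjusted p = 6.2e-10, and 0.00964 with an estimated correlation). Of these, 0 of 17 were called in the authors' deposited table, and 3 were lower adjusted over the list alone. In the SON deletion, INHBE, a hepatokine gene of the activin family, was higher and the non-coding RNA LINC00649 lower with both hgRNAs. INHBE was also called higher with both hgRNAs of SFPQ, so its rise was not particular to SON. The SON hgRNAs carry the same Cas12a guide and overlapping Cas9 guides, so their agreement is not that of independent reagents. The counts in the authors' deposited table were 6 higher and 5 lower with SON hgRNA 1, and 5 higher and 7 lower with hgRNA 2. ATF4 targets were higher as a set with SON hgRNA 1 (limma, adjusted p = 3.4e-06, and 0.036 with an estimated correlation), with 0 of 26 called in the authors' deposited table and 8 higher adjusted over the list alone.

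Each knockout served as the loss of function against which its gene's intronic deletion could be set. In the SON knockout 36 splicing events were higher and 182 lower, mainly cassette exons with lower inclusion. Of 172 called exons, 16 were higher and 156 lower, and of 25 called introns, 9 were higher and 16 lower. An intron (HsaINT1022596, chromosome 2) of MAT2A, which makes S-adenosylmethionine, was retained at 20.2% ± 15.6 (SD, n = 2) against 58.2% ± 3.03 (SD, n = 4) (limma, adjusted p = 0.01). The call was lost without SON knockout replicate 1, where the difference was −27.0 points. The SRRM2 intron that holds the targeted exon was retained at 18.2% ± 13.4 (SD, n = 2) against 56.2% ± 3.10 (SD, n = 4) (limma, adjusted p = 0.0148). That call was lost without SON knockout replicate 1, at −28.6 points. An intron of PPP1R37, a phosphatase regulator, rose to 27.9% ± 5.61 (SD, n = 2) from 6.40% ± 2.59 (SD, n = 4) (limma, adjusted p = 0.00331), a call lost without SON knockout replicate 1, at 17.5 points. The duplicates lay far apart for introns held at high levels: over 1941 detained-like introns the mean PSI was 21.8% in replicate 1 and 30.6% in replicate 2.

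Expression in the SON knockout changed at 1886 higher and 1286 lower genes in the authors' deposited table. Genes of the actin cytoskeleton rose, with 21 of 37 actin and SRF targets higher and 0 lower in the authors' deposited table (25 and 0 adjusted over the list alone; limma set test, adjusted p = 1.6e-10, and 0.0248 with an estimated correlation). Examples in the authors' deposited table were the cytoplasmic actins ACTB at 0.86 and ACTG1 at 0.83. CCN2, a matrix protein and YAP target, rose by 1.67 on the log2 scale in the authors' deposited table. Of 31 immediate-early genes in the authors' deposited table, 12 were higher, such as the growth-factor response gene EGR1 at 1.72, and 1 was lower (14 and 1 adjusted over the list alone; limma set test, adjusted p = 2.3e-05, and 0.131 with an estimated correlation). Of 16 YAP targets in the authors' deposited table, 7 were higher and 0 lower (9 and 1 adjusted over the list alone; limma set test, adjusted p = 5.8e-08, and 0.153 with an estimated correlation). Of 35 core spliceosome genes in the authors' deposited table, 10 were higher and 0 lower (14 and 0 adjusted over the list alone; limma set test, adjusted p = 0.00111, and 0.106 with an estimated correlation). Of 16 factors of nonsense-mediated decay in the authors' deposited table, 6 were higher and 0 lower (7 and 0 adjusted over the list alone; limma set test, adjusted p = 0.0144, and 0.697 with an estimated correlation).

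The SRRM2 knockout raised intron retention and lowered exon inclusion at the events it changed. Of 419 called events, 142 were introns (122 higher, 20 lower), 199 were cassette exons (22 of them higher) and 59 were alternative 5′ splice sites (31 higher, 28 lower). An intron (HsaINT0020864, chromosome 15) of KNSTRN, a kinetochore protein, was retained at 79.4% ± 3.83 (SD, n = 2) against 34.9% ± 2.30 (SD, n = 4), a difference of 44.6 points (SE 5.67; limma, adjusted p = 2.3e-05). An intron (HsaINT1027012, chromosome 16) of PKD1, the membrane receptor polycystin 1, was retained at 74.2% ± 1.95 (SD, n = 2) against 31.4% ± 6.39 (SD, n = 4) (SE of the difference 4.73; limma, adjusted p = 1.2e-06). In the other direction, an intron of SNHG1, a host of small nucleolar RNAs, was retained at 22.1% ± 9.36 (SD, n = 2) against 52.0% ± 2.76 (SD, n = 4) (limma, adjusted p = 1.7e-04). An exon of SLC41A1, a magnesium transporter, was included at 39.6% ± 6.92 (SD, n = 2) against 86.4% ± 11.2 (SD, n = 4) (limma, adjusted p = 3.6e-04). An intron of SRRT rose to 41.8% ± 4.53 (SD, n = 2) from 24.4% ± 2.64 (SD, n = 4) (limma, adjusted p = 0.0141), a call lost without SRRM2 knockout replicate 2, at 14.3 points. Without SRRM2 knockout replicate 1 the count of called events was 1710. Detained-like introns averaged 22.1% in replicate 1 and 36.04% in replicate 2.

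Expression in the SRRM2 knockout changed at 2356 higher and 1836 lower genes in the authors' deposited table. Actin and SRF targets rose again, with 22 of 37 higher and 1 lower in the authors' deposited table (26 and 2 adjusted over the list alone; limma set test, adjusted p = 1.5e-11, and 0.0194 with an estimated correlation). TAGLN rose by 1.85 and ACTG1 by 1.06 on the log2 scale in the authors' deposited table. HMOX1, which degrades haem, rose by 1.60 on the log2 scale in the authors' deposited table, and MYB, a transcription factor of blood progenitors, fell by 1.48. Of 57 replication-dependent histone genes in the authors' deposited table, 24 were higher and 0 lower (36 and 0 adjusted over the list alone; limma set test, adjusted p = 3.7e-08, and 0.225 with an estimated correlation). Of 26 ATF4 targets in the authors' deposited table, 13 were higher and 1 lower (14 and 1 adjusted over the list alone; limma set test, adjusted p = 0.00231, and 0.224 with an estimated correlation). Of 31 immediate-early genes in the authors' deposited table, 15 were higher and 2 lower (17 and 3 adjusted over the list alone; limma set test, adjusted p = 6.4e-06, and 0.102 with an estimated correlation). Of 16 factors of nonsense-mediated decay in the authors' deposited table, 9 were higher and 0 lower (limma set test, adjusted p = 0.0032, and 0.58 with an estimated correlation).

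In the PFN1 knockout, sterol synthesis genes were lower as a set, with 0 of 24 higher and 6 lower in the authors' deposited table (0 and 11 adjusted over the list alone; limma set test, adjusted p = 1.7e-07, and 0.00144 with an estimated correlation). INSIG1, a sensor of cholesterol, was at −0.69 on the log2 scale in the authors' deposited table. ATF4 targets were lower as a set, with 1 of 26 higher and 5 lower in the authors' deposited table (1 and 12 adjusted over the list alone; limma set test, adjusted p = 3.4e-07, and 0.0207 with an estimated correlation). Genes of the G1/S transition rose as a set, with 2 of 38 higher and 0 lower in the authors' deposited table (3 and 0 adjusted over the list alone; limma set test, adjusted p = 8.6e-04, and 0.0263 with an estimated correlation). Actin and SRF targets were lower as a set at the preset correlation only, with 0 of 37 higher and 4 lower in the authors' deposited table (0 and 7 adjusted over the list alone; limma set test, adjusted p = 0.00572, and 0.497 with an estimated correlation). The 4 lower genes include PFN1, the gene knocked out, which adds to the set result. TAGLN was at −1.63 and the myosin light chain MYL9 at −2.39 on the log2 scale in the authors' deposited table. Of 19 heat shock genes in the authors' deposited table, 0 were higher and 4 lower, such as HSPA1A at −0.94, whose reads can be shared with HSPA1B (4 lower adjusted over the list alone; limma set test, adjusted p = 6.2e-04, and 0.393 with an estimated correlation). In all, 490 genes were higher and 342 lower in the authors' deposited table.

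Of 13 splicing events called in the PFN1 knockout, 4 were higher and 9 lower. An exon (HsaEX0020456, chromosome 19) of DNM2, a GTPase of endocytosis, was included at 21.7% ± 0.368 (SD, n = 2) against 7.07% ± 0.993 (SD, n = 4) (SE of the difference 1.84; limma, adjusted p = 2.3e-04). A long exon (HsaEX0042924, chromosome 14) of NIN, the centrosomal protein ninein, was included at 55.0% ± 3.47 (SD, n = 2) against 85.5% ± 3.88 (SD, n = 4) (SE of the difference 3.56; limma, adjusted p = 1.1e-04). The count was 118 without PFN1 knockout replicate 1, 55 without replicate 2, 4 without intergenic control hgRNA 1 replicate 1 and 8 without intergenic control hgRNA 2 replicate 2. Detained-like introns averaged 25.3% in replicate 1 and 32.4% in replicate 2.

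In the SRRT knockout 19 splicing events were called, 9 higher and 10 lower. An intron (HsaINT0088058, chromosome X) of KIF4A, a mitotic kinesin, was retained at 28.1% ± 1.64 (SD, n = 2) against 9.06% ± 2.80 (SD, n = 4) (SE of the difference 1.71; limma, adjusted p = 1.7e-07). An exon of APTX, a DNA end-processing enzyme, was included at 36.8% ± 1.06 (SD, n = 2) against 14.5% ± 1.78 (SD, n = 4) (SE of the difference 3.17; limma, adjusted p = 0.00126). The DNM2 exon was higher here too, at 21.5% ± 4.82 (SD, n = 2) (limma, adjusted p = 1.9e-04). An exon of HNRNPH1, itself a splicing regulator, was lower, at 58.1% ± 1.99 (SD, n = 2) against 76.8% ± 4.47 (SD, n = 4) (limma, adjusted p = 0.00329), a call lost without SRRT knockout replicate 2, at −17.3 points. The count was 274 without SRRT knockout replicate 1 and 93 without replicate 2. Detained-like introns averaged 21.8% in replicate 1 and 32.4% in replicate 2.

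Expression in the SRRT knockout changed at 1268 higher and 1162 lower genes in the authors' deposited table. Contractile and YAP-driven genes rose, with 19 of 37 actin and SRF targets higher and 0 lower in the authors' deposited table (20 and 0 adjusted over the list alone; limma set test, adjusted p = 1.1e-12, and 0.0123 with an estimated correlation). Of 16 YAP targets in the authors' deposited table, 9 were higher and 1 lower (10 and 1 adjusted over the list alone; limma set test, adjusted p = 2.4e-13, and 0.0263 with an estimated correlation). ACTG2, ANKRD1 and TAGLN rose by 1.82, 1.79 and 1.64 on the log2 scale in the authors' deposited table. Of 31 immediate-early genes in the authors' deposited table, 16 were higher, such as EGR1 at 1.67, and 0 lower (18 and 1 adjusted over the list alone; limma set test, adjusted p = 1.1e-09, and 0.0153 with an estimated correlation). TXNIP, which inhibits thioredoxin, fell by 1.37 on the log2 scale in the authors' deposited table. Of 24 sterol synthesis genes in the authors' deposited table, 0 were higher and 5 lower (0 and 7 adjusted over the list alone; limma set test, adjusted p = 0.00431, and 0.131 with an estimated correlation).

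With all libraries in 1 fit, the knockdowns called the most splicing events, although the SRRM2 knockout called more than 2 of them without its replicate 1. In fits of the 2 compared conditions only, limma still called events in the SRSF3 knockdown, 17 in the SRRM2 knockout and 1 in the SRRT knockout, and 0 in the other knockouts, the SRRM2 and SFPQ knockdowns and the deletions. In the SRSF3 knockdown 5530 events were called, 2553 higher and 2977 lower. Of 2845 called cassette exons 984 were higher and 1861 lower, and of 1570 called introns 1007 were higher and 563 lower. Inclusion of an exon (HsaEX1007606, chromosome 14) of CCNK, the cyclin of the transcription kinases CDK12 and CDK13, was 0.445% ± 0.629 (SD, n = 2) against 100% (n = 2) (SE of the difference 0.552; limma, adjusted p = 1.5e-43). An exon of SUPT6H, a histone chaperone of transcribing polymerase, was included at 1.25% ± 0.177 (SD, n = 2) against 100% (n = 2) (limma, adjusted p = 8.7e-41). In the other direction, an exon of LRRFIP2 was included at 92.1% ± 2.40 (SD, n = 2) against 4.23% ± 2.84 (SD, n = 2) (limma, adjusted p = 8.8e-21). An intron (HsaINT1028151, chromosome 6) of PRRC2A was retained at 93.0% ± 0.523 (SD, n = 2) against 6.11% ± 0.693 (SD, n = 2) (limma, adjusted p = 7.1e-24), and an intron of GLG1 fell to 15.6% ± 0.198 (SD, n = 2) from 90.3% ± 1.74 (SD, n = 2) (limma, adjusted p = 7.0e-26). The SRSF3 intron that holds the deleted segment was retained at 17.7% ± 0.0849 (SD, n = 2) against 3.41% ± 0.396 (SD, n = 2) (limma, adjusted p = 1.2e-13).

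Expression in the SRSF3 knockdown changed at 5370 higher and 6180 lower genes in the authors' deposited table. Cell cycle genes fell nearly as a whole. Of 38 G1/S genes in the authors' deposited table, 0 were higher and 36 lower, such as the replication factors CDC45 at −3.39 and MCM10 at −2.89 (0 and 36 adjusted over the list alone; limma set test, adjusted p = 1.1e-23, and 2.4e-17 with an estimated correlation). Of 32 G2/M genes in the authors' deposited table, 0 were higher and 31 lower, such as the mitotic kinases BUB1 at −3.01 and PLK1 at −2.34 (0 and 31 adjusted over the list alone; limma set test, adjusted p = 2.2e-10, and 0.0387 with an estimated correlation). Of 57 replication-dependent histone genes in the authors' deposited table, 0 were higher and 44 lower (0 and 45 adjusted over the list alone; limma set test, adjusted p = 4.3e-07, and 0.311 with an estimated correlation). Splicing factors fell too. Of 14 SR protein genes in the authors' deposited table, 2 were higher and 12 lower, such as SRSF1 at −1.82 and SRSF2 at −1.66 (limma set test, adjusted p = 0.00352, and 0.204 with an estimated correlation). The 12 include SRSF3, the target of the siRNA, which adds to the set result. Of 26 genes of hnRNPs and PTB proteins in the authors' deposited table, 2 were higher and 19 lower (limma set test, adjusted p = 4.2e-04, and 0.224 with an estimated correlation). Of 82 ribosomal protein genes in the authors' deposited table, 2 were higher and 51 lower (2 and 53 adjusted over the list alone; limma set test, adjusted p = 0.0244, and 0.926 with an estimated correlation). Of 15 paraspeckle genes in the authors' deposited table, 1 was higher and 9 lower (limma set test, adjusted p = 0.0361, and 0.545 with an estimated correlation). Among the largest rises in the authors' deposited table were the collagens COL1A2 at 7.62 and COL3A1 at 5.93 and the transcription factor MAF at 8.76. Of 9 fibroblast genes in the authors' deposited table, 5 were higher and 1 lower (limma set test, adjusted p = 0.00136, and 0.17 with an estimated correlation). TDGF1, a co-receptor of Nodal, fell by 5.99 on the log2 scale in the authors' deposited table.

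In the SRRM2 knockdown intron retention rose and exon inclusion fell. Of 1520 called events, 769 were introns (720 higher, 49 lower) and 465 were cassette exons (104 higher, 361 lower). An intron (HsaINT0146050, chromosome 17) of SCO1, a copper chaperone of cytochrome oxidase, was retained at 57.0% ± 1.02 (SD, n = 2) against 3.43% ± 0.849 (SD, n = 2) (SE of the difference 3.19; limma, adjusted p = 4.5e-13). An intron of PISD, which makes phosphatidylethanolamine in mitochondria, was retained at 77.3% ± 5.57 (SD, n = 2) against 22.1% ± 0.721 (SD, n = 2) (limma, adjusted p = 3.3e-05). An exon of FAM189B was included at 36.1% ± 5.48 (SD, n = 2) against 93.9% ± 3.49 (SD, n = 2) (limma, adjusted p = 1.7e-11). The long NIN exon was lower here too, as in the PFN1 knockout, at 39.4% ± 1.02 (SD, n = 2) against 91.0% ± 4.41 (SD, n = 2) (limma, adjusted p = 5.6e-10). Without siRNA control replicate 1 the count was 957. ATF4 targets fell, with 0 of 26 higher and 15 lower in the authors' deposited table, such as the cystine transporter SLC7A11 at −1.46 and DDIT4 at −1.54 (0 and 17 adjusted over the list alone; limma set test, adjusted p = 2.5e-07, and 0.0201 with an estimated correlation). Of 16 YAP targets in the authors' deposited table, 2 were higher and 9 lower, with ANKRD1 at −4.49 (4 and 11 adjusted over the list alone; limma set test, adjusted p = 0.0249, and 0.697 with an estimated correlation). In all, 2283 genes were higher and 2992 lower in the authors' deposited table.

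The SFPQ knockdown raised both the inclusion of exons and the retention of introns. Of 1691 called events, 924 were cassette exons (718 higher, 206 lower) and 584 were introns (515 higher, 69 lower). An exon (HsaEX0038967, chromosome 2) of MFF, a mitochondrial fission factor, was included at 88.3% ± 12.2 (SD, n = 2) against 10.99% ± 0.318 (SD, n = 2) (SE of the difference 3.00; limma, adjusted p = 3.3e-19). An intron of NOTCH1, a receptor of cell fate decisions, was retained at 62.2% ± 5.40 (SD, n = 2) against 12.6% ± 4.61 (SD, n = 2) (limma, adjusted p = 4.6e-10). An exon of WSB1, part of a ubiquitin ligase, fell to 3.96% ± 0.396 (SD, n = 2) from 66.9% ± 1.63 (SD, n = 2) (limma, adjusted p = 1.9e-04). Introns of SFPQ itself rose, with 61.9% ± 7.29 (SD, n = 2) against 11.5% ± 4.29 (SD, n = 2) for HsaINT0148688 (limma, adjusted p = 8.5e-18).

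Expression in the SFPQ knockdown changed at 3378 higher and 4034 lower genes in the authors' deposited table. Among the largest falls in the authors' deposited table were the neuronal membrane protein GPM6A at −7.80, the cadherin CDH10 at −6.84 and the adhesion molecule CADM1 at −6.07. Of 6 neuronal genes in the authors' deposited table, 0 were higher and 4 lower (0 and 5 adjusted over the list alone; limma set test, adjusted p = 0.0167, and 0.194 with an estimated correlation). With 15488 genes in 5 classes of length, the class of longest genes, above 88250 bp, had a median log2 fold change of −0.41 in the authors' deposited table, and the class of shortest genes had 0. Spearman's rho with length was −0.193 across genes, which are not independent replicates, and −0.172 in the SRRM2 knockdown. Of 23 interferon-response genes in the authors' deposited table, 10 were higher, such as IFITM1 at 3.51, and 0 lower (11 and 0 adjusted over the list alone; limma set test, adjusted p = 0.00654, and 0.194 with an estimated correlation). Of 31 immediate-early genes in the authors' deposited table, 16 were higher and 1 lower (18 and 1 adjusted over the list alone; limma set test, adjusted p = 9.3e-04, and 0.233 with an estimated correlation). Of 37 actin and SRF targets in the authors' deposited table, 1 was higher and 20 lower (1 and 20 adjusted over the list alone; limma set test, adjusted p = 0.0055, and 0.497 with an estimated correlation). LEFTY2, an antagonist of Nodal, rose by 5.55 on the log2 scale in the authors' deposited table.

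The remaining fixed lists showed less. In the authors' deposited table, 24 genes of cap binding and the exosome were higher as a set with SRRT deletion hgRNA 1 (limma, adjusted p = 0.0244, and 0.414 with an estimated correlation), with 0 of them called singly. Speckle proteins were lower as a set with SRRM2 deletion hgRNA 1 (limma, adjusted p = 0.00245, and 0.545 with an estimated correlation), with 0 of 29 called in the authors' deposited table, and with SRSF3 deletion hgRNA 2 (limma, adjusted p = 0.00746, and 0.621). Blood genes, 6 of them above the expression minimum, were lower as a set in 3 comparisons, at an adjusted p as low as 0.024 (limma; 0.193 with an estimated correlation), with 0 called in the authors' deposited table in PFN1 deletion hgRNA 1. Pooled levels of the blood genes PTPRC and HBB stayed at or below 0.08 and 0.03 RPKM in the authors' deposited table. CD34 reached 0.50 RPKM and was called in 6 comparisons, and HBG1 stood at 1.57 RPKM in the intergenic control and reached 4.41 in the SRRM2 knockdown in the authors' deposited table. The limma set test called 0 comparisons for 5 lists, with smallest adjusted p values of 0.137 for chaperones of the endoplasmic reticulum, 0.13 for p53 targets, 0.106 for hypoxia and glycolysis genes, 0.106 for mitochondrial RNAs and 0.0871 for genes known to need SON for splicing.

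Detained introns stay in polyadenylated nuclear transcripts and are spliced late, and the mean retention over introns with a PSI of at least 15 was used to ask whether they shifted together. In the intergenic controls it was 31.3% ± 1.23 (SD, n = 4) over 1941 introns. It was 28.6% ± 1.28 (SD, n = 4) in the PFN1 deletion, 29.9% ± 0.639 (SD, n = 4) in the SFPQ deletion, 29.9% ± 2.44 (SD, n = 4) in the SRRM2 deletion and between 30.39% and 30.98% in the other 3. The knockouts averaged 28.9% ± 4.99 (SD, n = 2) for PFN1, 26.2% ± 6.24 for SON, 29.1% ± 9.85 for SRRM2 and 27.1% ± 7.54 for SRRT. Over 1781 introns the siRNA controls averaged 33.9% ± 3.12 (SD, n = 2), against 30.8% ± 0.67 with the SRSF3, 37.6% ± 2.11 with the SRRM2 and 36.2% ± 0.109 with the SFPQ siRNA. No comparison passed the exact two-sided permutation test, with adjusted p from 0.578 to 0.771 over 13 comparisons. The smallest p that the design allows was 0.0286 for deletions, 0.0667 for knockouts and 0.333 for knockdowns, before adjustment. So no comparison could reach 0.05 once adjusted over 13, and the outcome says nothing for or against a shift. The sign of the difference flipped without SON deletion hgRNA 2 replicate 1 (0.0637 points for SON), without intergenic control hgRNA 1 replicate 1 or SRRT deletion hgRNA 2 replicate 1 (0.113 and 0.182 for SRRT), and without replicate 1 of the PFN1, SRRM2 or SRRT knockout (1.12, 4.76 and 1.14).

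**Figure D3:**
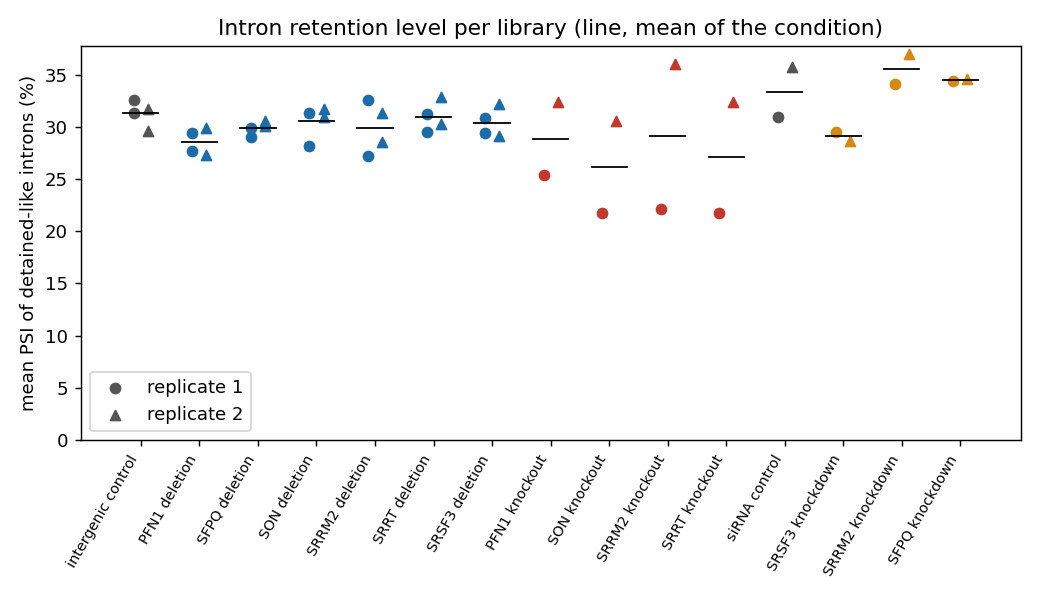
Points give the mean PSI in percent over detained-like introns for each library by condition, with the marker showing the replicate number and the line the mean of the condition. In each of the 4 knockouts replicate 1 lies lower, at 21.8% to 25.3%, than replicate 2, at 30.6% to 36.04%.

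Each deletion was set against the loss of the same gene to ask how far it acted alike. By limma's test of the difference, the change differed between deletion and knockout at 18 events for PFN1, 78 for SON, 258 for SRRM2 and 13 for SRRT. It differed between deletion and knockdown at 4338 events for SRSF3, 674 for SRRM2 and 1256 for SFPQ. Across events, which are not independent replicates, changes in the SRRM2 deletion correlated with those in the SRRM2 knockdown at r = 0.130 (−0.083 for hgRNA 1 and 0.263 for hgRNA 2 over fewer events), where unchanged groups gave −0.003. For SRSF3 r was 0.041 (−0.001 for unchanged groups) and for SFPQ −0.010 (−0.006). With knockouts, which share controls with the deletions, r was 0.419 for PFN1 (0.406 for unchanged groups), 0.475 for SON (0.412), 0.454 for SRRM2 (0.400) and 0.395 for SRRT (0.404). With the controls split by hgRNA, r was 0.048 and 0.102 for PFN1, 0.174 and 0.142 for SON, 0.153 and 0.161 for SRRM2, and 0.058 and 0.065 for SRRT. Knockout replicates varied with those of the siRNA control of the same number, at r of 0.176 to 0.273. The SRRM2 knockout and knockdown, with separate controls, shared 75 higher and 69 lower events, where independent lists would share 2.06 and 1.60, and correlated at r = 0.348 (0.018 for unchanged groups). The SON and SRRM2 knockouts shared 9 higher and 41 lower events and differed at 196. They share controls, and their changes correlated at r = 0.495 (0.339 for unchanged groups), and at 0.274 and 0.304 with the controls split by hgRNA. Knockout libraries with the same number also varied together, at r of 0.318 to 0.510, so these values include a shared variation of replicates.

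Genes between each targeted gene and the telomere of its arm were compared with the same regions in the deletions of the other 5 genes, a comparison chosen after the data were seen. Medians of log2 fold change in the authors' deposited table ranged from −0.11 to −0.40 over the 12 hgRNAs of the gene itself, and the same regions had a median of −0.01 over the other deletions. For PFN1, 20 of the 34 genes called lower with hgRNA 1 in the authors' deposited table lay on the telomeric side of 17p, where 0.177 would lie by chance. For SRSF3 hgRNA 2 it was 11 of 16 lower genes on 6p, where 0.347 would lie by chance, and for SFPQ hgRNA 1 it was 36 of 244 on 1p, where 6.38 would lie by chance. For SRRM2 it was 0 of 4 with hgRNA 1, 18 of 937 with hgRNA 2 (7.63 by chance) and 15 of 1367 in the knockout (11.1 by chance). With SFPQ hgRNA 2 and SRRT hgRNA 2, 0 of the genes placed were called lower.

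**Figure D4:**
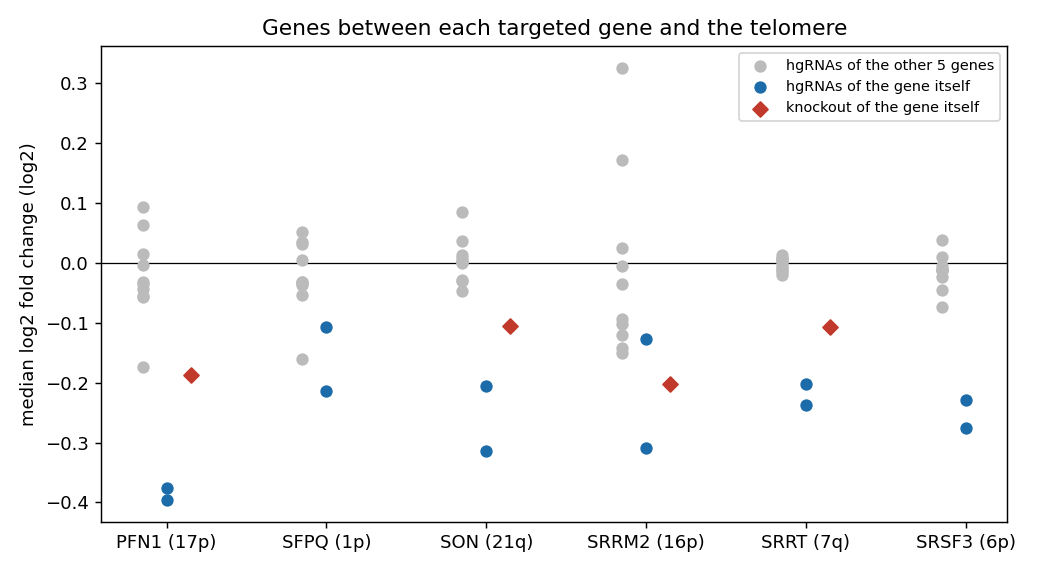
Points give the median log2 fold change of the genes between each targeted gene and its telomere, for hgRNAs of the other 5 genes (grey), hgRNAs of the gene itself (blue) and the knockout of the gene itself (red diamonds). The blue points lie between −0.11 and −0.40, and the lowest grey point at −0.17.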

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

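The tests of the chromosome arm, of depth, of a handling batch, of shared controls and of the editing rate, and the counts over other groupings of libraries, were chosen after the results were seen. The tests of unspliced RNA, of trends, of a loss of SRRM2 function and of a response common to knockouts were planned before theirs.

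In 48 groups of 4 values checked for a library far from the others, 3 exceeded Dixon's 95% value for 4 values, and chance alone picks out about 1 in 20 groups. They were the median of informative reads per intron in the PFN1 deletion (gap over range 0.836), retention of SFPQ intron HsaINT0148681 in the intergenic controls (0.871) and retention of SFPQ intron HsaINT0148682 in the SFPQ deletion (0.909). Groups that responded differently under the same contrast were picked out by limma's test of the difference. The hgRNAs of the SRRM2 deletion differed at 81 events and those of the SRSF3 deletion at 4. Deletion and knockout differed at 18 events for PFN1, 78 for SON, 258 for SRRM2 and 13 for SRRT. Deletion and knockdown differed at 4338 events for SRSF3, 674 for SRRM2 and 1256 for SFPQ.

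Other groupings of the same 8 libraries were counted for each deletion, 35 in all. They were first fitted on the 8 libraries alone, where the real groupings of SON and SRRM2 called 0 events, and then with the other 36 libraries adding to the estimate of spread, as in the report. For SRRM2 the real grouping called 4 events, 2 of them mirror sites of 1 exon, and no other called more than 0, so 1 of 35 reached it, the lowest share possible. Since the second form was adopted after the first had called 0, and 6 deletions were tested, chance is not taken as excluded. For SON, chance cannot be excluded, since the real grouping called 1 event, the highest other also called 1, and 4 of 35 called as many. For PFN1, SFPQ, SRRT and SRSF3 the real grouping called 0, so all 35 called as many, and the highest other called 2, 2, 1 and 1.

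In all 4 knockouts replicate 1 retained fewer detained-like introns than replicate 2, by ratios of 1.28 to 1.63. The reads argued against depth as the cause, since the ratio of median reads, replicate 1 to 2, lay between 0.959 and 1.126. Introns retained under 2% also gained in replicate 2, by at least 2.01-fold, which met the prediction for unspliced precursor or genomic DNA reads spread over all introns. In points these gains were small, from 0.497% to 0.999% for PFN1, 0.33% to 0.916% for SON, 0.436% to 1.14% for SRRM2 and 0.378% to 1.07% for SRRT. Detained-like introns rose from 25.3% to 32.4%, 21.8% to 30.6%, 22.1% to 36.04% and 21.8% to 32.4%. Reads spread evenly would add about as many points to both, so these values argue against them as the main cause. The differences between replicates correlated between every pair of knockouts, at 0.318 or more, as a handling batch shared by libraries of the same number could produce. No biological explanation was tested, and biological variation between cultures stays open.

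The expression changes of some unrelated deletions were alike, and others were not, with r from 0.040 to 0.619 over 60 pairs in the authors' deposited table. The pair weighed here, PFN1 hgRNA 1 and SFPQ hgRNA 1, was among the highest at r = 0.604. Whether shared controls produced this cannot be told apart from a real likeness: the covariance of 0.1001 was the highest of the 60 pairs (median 0.0293), so its excess over the median excludes nothing, and simulated unchanged groups gave 0.1145, above all 60. The simulated groups were the first form of this test, and the median replaced them after that result. Removing trends with gene length, GC content and level left r at 0.611 against 0.590 before, over 13270 genes, which argues against those trends for this pair. A common response to cutting or a shared culture effect may remain. Neither was tested, nor was this pair on pooled RPKM.

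SRRM2 hgRNA 2 changed more genes and events than hgRNA 1. Whether editing was rarer with hgRNA 1 cannot be told from the targeted intron, although it moved 24.1 points further with hgRNA 1. The hgRNAs remove different segments, so the shift per edited cell may differ between them. The same intron was also lower in the SON knockout, whose guides do not target SRRM2. Editing itself was not measured here. Changes with hgRNA 2 correlated with the SRRM2 knockdown at 0.263 and those with hgRNA 1 at −0.083, a gap of 0.346 that may point to a loss of SRRM2 function with hgRNA 2. The knockdowns of SFPQ (0.160 against −0.079) and SRSF3 (0.142 against 0.016), which share the siRNA controls, showed gaps in the same direction, so the pattern is not specific to SRRM2. A response common to the knockouts and a specific one cannot be told apart, since r with the SRRM2 knockout exceeded that with the PFN1 knockout by 0.0884, between the bounds set for the test. The telomeric side of 16p, which was also lower with hgRNA 2 (median −0.31, against −0.13 with hgRNA 1), may contribute.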

How the results depend on the processing

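The fits with knockout libraries left out, the fit without introns of unbalanced junction reads and the log2 ratio of pooled RPKM were chosen after the data were seen, and the other alternatives before. For the count of called splicing events, most deletions kept a count near 0 under all of them. On the logit scale of PSI the count was 0 for the SON and 0 for the SRRM2 deletion, and 1 for the PFN1, 100 for the SON, 96 for the SRRM2 and 7 for the SRRT knockout. With a minimum difference of 15 points it was 0 for the SON deletion and 8, 134, 217 and 9 for the PFN1, SON, SRRM2 and SRRT knockouts, which follows from the stricter minimum. With a coverage score of OK or better it was 5 for the PFN1 knockout. In fits of the 2 compared conditions only, where fewer libraries estimate the spread, it was 0 for the SON and SRRM2 deletions, 0, 0, 17 and 1 for the PFN1, SON, SRRM2 and SRRT knockouts, and 0 and 0 for the SRRM2 and SFPQ knockdowns. With each hgRNA as a group it was 3, 7 and 1 for the SON, SRRM2 and SRSF3 deletions and 30 and 35 for the PFN1 and SRRT knockouts. Without all knockout libraries it was 3 for the SON deletion. Without replicate 1 of all knockouts it was about 1.7e+02 (121 higher and 50 lower) for PFN1 and 363 for SON, and without replicate 2 it was 68 and 266 for PFN1 and SRRT. The splicing changes per perturbation: SRRM2 knockout numbered 1945, and the splicing changes per perturbation: SRRT knockout 368, without replicate 1 of all knockouts. The splicing changes per perturbation: SON knockout numbered 398 without replicate 2 of all knockouts. The splicing changes per perturbation: SRSF3 knockdown numbered 1431 in the fit of the 2 compared conditions only. On the logit scale, the splicing changes per perturbation: SRRM2 knockdown numbered 464 and the splicing changes per perturbation: SFPQ knockdown 1118, and with a minimum difference of 15 points 945 and 1097. Where no construction of the alternative shows it, the cause was not tested.

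Leaving out each library in turn gave counts of 0 to 0 for the PFN1, 0 to 1 for the SFPQ, 1 to 2 for the SON, 3 to 5 for the SRRM2, 0 to 1 for the SRRT and 0 to 4 for the SRSF3 deletion. They were 4 to 118 for the PFN1, 152 to 275 for the SON, 309 to 1710 for the SRRM2 and 15 to 274 for the SRRT knockout, and 4963 to 5857, 957 to 1813 and 1332 to 1728 for the SRSF3, SRRM2 and SFPQ knockdowns. A lone library left in a group was assumed to vary like the other groups. Targeted events called numbered 14, and 11 to 16 with a library left out. The difference in retention of detained-like introns, in points, ranged from −3.27 to −2.29 for the PFN1, −1.95 to −0.975 for the SFPQ, −1.29 to 0.0637 for the SON, −2.27 to −0.507 for the SRRM2, −0.911 to 0.182 for the SRRT and −1.47 to −0.472 for the SRSF3 deletion. It ranged from −5.94 to 1.12 for the PFN1, −9.53 to −0.711 for the SON, −9.17 to 4.76 for the SRRM2 and −9.51 to 1.14 for the SRRT knockout, and from −5.35 to −0.942, 1.43 to 5.84 and 0.0253 to 4.44 for the SRSF3, SRRM2 and SFPQ knockdowns. Intron minimums of 10 and 30 and the median over introns reversed the sign of none of the 13 differences in retention level. Without intergenic control hgRNA 1 replicate 1 the SRRT deletion reversed, at 0.113.

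Requiring a fold change of at least 2 left, in the authors' deposited table, 38 and 3 genes for PFN1, 118 and 15 for SFPQ, 4 and 3 for SON, 3 and 347 for SRRM2, 4 and 2 for SRRT and 13 and 19 for SRSF3 with hgRNA 1 and 2. It left 131, 546, 747 and 421 in the PFN1, SON, SRRM2 and SRRT knockouts and 7031, 1599 and 3426 in the SRSF3, SRRM2 and SFPQ knockdowns. With an estimated correlation the gene lists called numbered 0 and 0 for PFN1, 0 and 1 for SFPQ, 1 and 0 for SON, 0 and 1 for SRRM2, 0 and 1 for SRRT and 1 and 1 for SRSF3 with hgRNA 1 and 2. They numbered 3, 1, 1 and 3 in the PFN1, SON, SRRM2 and SRRT knockouts and 2, 1 and 0 in the SRSF3, SRRM2 and SFPQ knockdowns. As the log2 ratio of pooled RPKM in the authors' deposited table, the targeted gene was at −0.64 with PFN1 deletion hgRNA 1, −2.56 as targeted gene expression: SFPQ in SFPQ knockdown, −0.0336 with SON deletion hgRNA 1, 0.0683 in the SON knockout, −0.60 with SRRM2 deletion hgRNA 1, −2.17 in the SRRM2 knockdown, −0.84 in the SRRM2 knockout, 0.33 with SRRT deletion hgRNA 2 and −0.52 in the SRRT knockout. The other 10 of 19 values moved by less.

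Of 76 named events, 29 lost their call on the logit scale, 64 in fits of the compared conditions, 2 with each hgRNA as a group, and 0 with a replicate block, and 2 of 59 with a score of OK or better. Of 24 results for targeted events, called or not, 6 lost a call on the logit scale and 16 in fits of the compared conditions. With a score of OK or better, 1 of 22 lost it. Of 4 in the knockouts, 2 lost a call without replicate 1 of all knockouts, and 1 lost and 1 gained it without replicate 2. The targeted SRRM2 intron HsaINT0159182 gained a call in the SRRM2 deletion without the knockout libraries, where its difference was −30.7 points. It also gained a call in the SRRM2 knockout with a replicate block and with each hgRNA as a group.

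The replicate block changed no count of splicing calls by over 1.5 times. Deviations of libraries with the same number correlated at a median of 0.00663 over 231 pairs of groups (−0.153 to 0.510), and between the 4 knockouts at 0.318 to 0.510. The numbers do not pair perturbed groups with their controls, but knockouts share variation by number with each other and, at 0.176 to 0.273, with the siRNA control. Not run, because the deposited expression table is pooled, were other size factors, another count test, no filter on low counts, a fit of the compared conditions, grouping by hgRNA, a replicate block and leaving out each library for expression, the targeted genes, the gene sets and the comparison of deletions with the loss of the gene by expression. Depth, at a median of 87 or more reads per intron, was not tested as a limit. Of simulated changes of 10 points, 62% to 80% passed the adjusted p, and 38% to 44% also met the minimum difference of 10 points.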

Other observations

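The tests of the chromosome arm in this part and their margin of 0.05 on the log2 scale were set after the results were seen.

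Gene length went with expression in opposite directions for the hgRNAs of 5 of the 6 genes. Spearman's rho with length across 15488 genes in the authors' deposited table was −0.262 with SFPQ hgRNA 1 and 0.141 with hgRNA 2, and −0.164 with SON hgRNA 1 and 0.203 with hgRNA 2. It was −0.050 and 0.197 for PFN1, −0.069 and 0.111 for SRRM2, and −0.076 and 0.196 for SRRT. For SRSF3 it was 0.030 and 0.184, of the same sign. Apart from SRSF3 hgRNA 1, the sign followed the hgRNA number across unrelated genes. A variation shared by groups with the same hgRNA number was not tested, and the results of single hgRNAs may include it. In the SRRT knockout it was −0.164. DCX, a neuronal microtubule protein, stood at 0.85 RPKM in the siRNA control and 15.2 in the SRSF3 knockdown in the authors' deposited table. COL3A1, a fibrillar collagen, stood at 0.69 and 38.9 RPKM in the authors' deposited table.

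Genes between the cut and the telomere were lower with both hgRNAs of all 6 genes, and loss of the chromosome arm beyond the cut in part of the cells may explain this. In all 12 comparisons the telomeric side lay below the genes within 20 Mb on the other side by more than 0.05, by gaps of −0.06 to −0.31 on the log2 scale. For SRRM2 hgRNA 1, with the smallest gap, a property of the region on 16p stays open. Of the 10 deletions of other genes, 5 had gaps on 16p as large (down to −0.156 with PFN1 hgRNA 2), all of them with hgRNA 2. With hgRNA 1 of the other genes the gaps there ran from −0.05537 (SRSF3) to 0.241 (SFPQ), against −0.05546 with SRRM2 hgRNA 1. In the siRNA knockdowns the gap on 16p was −0.121 for SRRM2, 0.142 for SFPQ and 0.243 for SRSF3. Over the 6 genes together a property of the regions themselves was argued against, since 1 of 720 assignments of regions to genes gave a mean as low as the real −0.25 (exact one-sided p = 0.00139), and the lowest other mean was −0.19. Beyond 5 Mb the median stayed below −0.05 in 8 of 8 comparisons of SFPQ, SON, SRRT and SRSF3, between −0.09 and −0.34, which argues against a local effect on neighbouring genes except for SFPQ hgRNA 1. For SFPQ hgRNA 1 a local effect cannot be told apart, since 1 of 10 deletions of other genes, SRRM2 hgRNA 2, had a median as low there (−0.155). For PFN1 and SRRM2 a local effect cannot either, since 0 of their comparisons had telomeric genes beyond 5 Mb. The Cas9 knockouts gave a mean of −0.15, with 1 of 24 assignments as low (exact one-sided p = 0.0417). The pattern was found and tested on the same data, and the copy number of the arms was not analysed here. If arms were lost, the lower level of VPS52 in the SRSF3 deletion may come in part from that loss, as may those of PFN1, METTL16 and NXN, where a local effect also stays open.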
